A study of Mus musculus with 5 samples.

How the data were processed

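Striatal RNA of 5 male FVB mice aged 12 months was measured on a single-colour mouse oligonucleotide array. Per the labels' protocols, all 5 mice carried a Huntington's disease (HD) transgene in which GFP was fused to exon 1 of human HTT with 84 CAG repeats, under a human ubiquitin promoter. In 3 of them, called HD_miR196a here, a precursor of the microRNA miR-196a was expressed from the same kind of promoter, and the other 2, called HD, lacked it. Groups and mouse numbers were taken from the sample titles and genotype labels. No mice without the HD transgene were analysed here, so no value below compares HD mice with healthy mice.

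The deposited values are linear intensities, 1 per probe and mouse, for 26423 probes. Per the labels, RNA was amplified and labelled with Cy5, and 2 technical repeats of each mouse were combined by the authors, so the mouse is the replicate and the repeats are not counted. The deposited intensities include values slightly below 0, so background had been subtracted. The scanner, the software and any scaling by the authors are not given in the sources used here. Deposited medians were 160.0, 166.3 and 166.2 in HD_miR196a mice 1 to 3 and 184.3 and 185.6 in HD mice 1 and 2. Whether this difference between the groups is one of scale, batch or biology was not tested, and quantile normalization removes it. Between 312 and 370 values per mouse were below 1, and at most 4 per mouse lay near the upper end of the scale.

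The tests, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. For linear values whose distributions differ they called for quantile normalization, and this was done, followed by a floor of 1 and a log2 transformation. Probes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 1.75 prior degrees of freedom), with the difference always HD_miR196a minus HD and a two-sided Benjamini-Hochberg adjusted p under 0.05 over all 26423 probes. All adjusted p-values of single genes below come from this fit unless another is named. The number of arrays limits the precision, and an exact permutation test of 3 against 2 mice has 10 splits and cannot give a p below 0.1.

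Gene names came from a table of the platform's probes. Of the probes, 20377 had 1 symbol, none had several and 6046 had none. Against RefSeq gene names of the assembly GRCm38.p6, 18213 of the symbols matched directly, 2126 through a synonym and 38 did not match, which gave 17742 genes. The coordinates of that table were not used, because the build behind the array is not given in the sources used here. Probe-level detection calls were not used here. As a measure of background, 544 probes of olfactory receptor genes, which are mostly silent in striatum, had a median of 32.6 and a 95th percentile of 308.4 (8.27 on the log2 scale). Over all probes, 59.9% had a mean below that 95th percentile.

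The gene lists, 30 in all, covered striatal neurons, other cell types and neighbouring regions, miR-196 targets from the literature, Hox clusters, and pathways linked to HD. The 29 with at least 5 measured genes were tested with camera of limma at its preset inter-gene correlation of 0.01, on the brightest probe of each gene. Camera with an estimated correlation and fry were run beside it. The rule for naming genes takes up to 12 probes per direction past the threshold, filled up where fewer passed with the smallest p among named probes whose groups did not overlap, above the lower quartile of level and over 0.3 in size on the log2 scale, the 2 members of each list with the smallest p, and a fixed set of HD and miR-196 genes. Other genes named below were chosen after their values were seen where the text says so, and other list members are given as examples of their list.

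The fit was tested on simulated data with the probe means of these arrays and limma's moderated variances shuffled over probes, so a probe's spread was not tied to its level. In each of 20 runs of the comparison of 3 with 2 mice, 200 of 26423 probes were changed, all with a mean above 6 on the log2 scale. It recovered 0.1% of changes of 0.5 on the log2 scale, 28.1% of changes of 1, 83.7% of changes of 2 and 95.2% of changes of 4, with 5.25 false calls per run. A simulated shift of the microglia list by 0.25 was called in 20 of 20 runs with the preset correlation and in 0 of 20 with the estimated one. Simulated probes varied independently, so these runs do not test the preset correlation for lists whose genes vary together. The estimated correlation was 0.4 for medium spiny neuron genes and 0.693 for myelin genes.

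The alternatives set beforehand were median centring, filters on dim probes, eBayes with trend and robust settings, the mouse number as a block, array weights, each mouse left out in turn, other thresholds, only named probes, and the mean of a gene's probes. A fit without an HD mouse keeps only 1 of them. For gene lists its mean is given without a p-value, though a call said to be lost there still rests on such a p. At the preset correlation camera takes genes nearly as replicates in every fit, also with all mice. Quantile normalization was also listed as an alternative and is the setting used. A planned test of miR-196 seed matches was not run, since 3' UTR sequences were not used here. Alternatives added after seeing the data were no scaling, a higher floor, the mean of the cortical neuron list as a covariate, leaving out the mouse numbered 1 in each group, and leaving out 13 probes that were off or on in 1 mouse only (with all mice and without HD mouse 1). Figures were drawn with matplotlib 3.10.9.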

Results

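The array profiled striatum, the brain region most affected in Huntington's disease, from 3 HD_miR196a mice and 2 HD mice. The comparison asks which transcripts differ when miR-196a is overexpressed in mice that carry mutant HTT. Deposited medians ranged from 160.0 to 185.6 between mice. After normalization the median absolute difference between mice, on the log2 scale, was 0.167 to 0.201 within HD_miR196a, 0.185 within HD and 0.162 to 0.213 between the groups. The closest pair was HD_miR196a mouse 1 and HD mouse 1, which belong to different groups.

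The genes named by rank were picked for a small p and groups that did not overlap. The rule takes up to 12 probes in each direction, so their directions are not a result. Acot8, a peroxisomal acyl-CoA thioesterase, measured 2.81 ± 0.59 (SD, n = 3) on the log2 scale in HD_miR196a mice and 9.71 ± 0.20 (SD, n = 2) in HD mice, and its limma adjusted p was 0.108. Tmeff1, a transmembrane protein with follistatin-like domains, measured 10.45 ± 0.01 against 11.22 ± 0.02, a difference of -0.76 ± 0.08 (SE, adjusted p = 0.639), while its brighter second probe differed by -0.12 ± 0.13. Cirbp, the cold-inducible RNA-binding protein, was at 12.03 ± 0.03 against 12.46 ± 0.03. In the other direction, the polo-like kinase gene Plk5 measured 10.84 ± 0.17 in HD_miR196a mice and 9.99 ± 0.14 in HD mice, and the diacylglycerol kinase gene Dgkd measured 11.52 ± 0.07 against 10.87 ± 0.20. None of these genes passed the threshold over all probes. Acot8 passed among the 19817 probes with the highest mean over the 5 mice (adjusted p = 0.0221). It cleared that filter, cut at 5.41, only through the HD mice. Tmeff1 passed with the floor at the olfactory receptor median (adjusted p = 0.0387).

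Across the array, limma called 0 of 26423 probes at an adjusted p under 0.05. At an unadjusted p under 0.05 it found 1099 probes, 558 higher and 541 lower in HD_miR196a mice, where 1321 would be expected by chance if no probe differed. The groups did not overlap at 20.3% of probes, and chance gives 20% for 3 against 2. In simulated data of this size, with variances shuffled over probes, the fit recovered 28.1% of changes of 1 on the log2 scale. With eBayes trend and robust settings 3 probes were called, of Acot8, Serpina9 and Lats2, the last 2 chosen after their values were seen (adjusted p = 0.0111, 0.0125 and 0.0111). Serpina9 was higher in HD_miR196a mice, at 6.54 ± 0.17 against 3.48 ± 0.12, both within the range of olfactory receptor probes. Of the 24 probes named by rank, 18 had means below the 95th percentile of olfactory receptor probes.

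**Figure D1:**
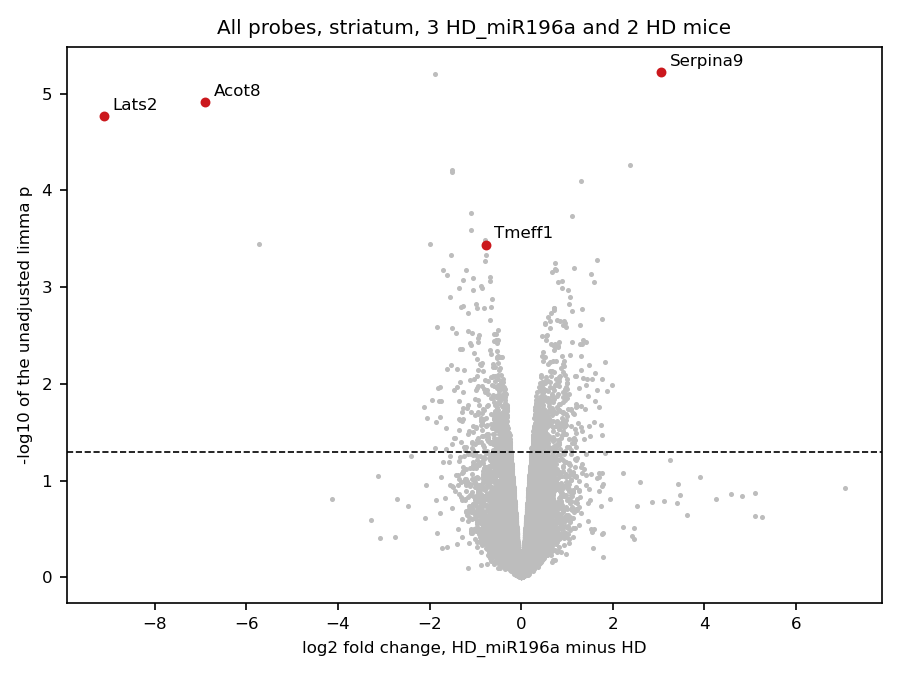
Each point is 1 of 26423 probes, with the log2 fold change (HD_miR196a minus HD) on the horizontal axis and minus log10 of the unadjusted limma p on the vertical axis. The dashed line marks an unadjusted p of 0.05, 1099 probes lie above it, and Acot8, Lats2, Serpina9 and Tmeff1 are in red.

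Genes that define medium spiny neurons, the main neuron type of the striatum, were mostly higher in HD_miR196a mice: 25 of 29 were higher and 4 were lower. The enkephalin precursor Penk measured 15.12 ± 0.11 (SD, n = 3) against 14.74 ± 0.02 (SD, n = 2), the dopamine receptor Drd1 13.04 ± 0.12 against 12.72 ± 0.03, and the phosphodiesterases Pde1b and Pde10a differed by 0.45 ± 0.12 and 0.60 ± 0.22 (SE). Rgs9, a regulator of G-protein signalling, differed by 0.54 ± 0.14 on its brighter probe and by -0.25 ± 0.12 on a dimmer one. No member passed the threshold, over all probes or adjusted over the list alone (smallest adjusted p = 0.168), and the groups did not overlap for 11 of the 29, where chance gives 20%. Camera placed the list above other genes with a mean of 0.12 (adjusted p = 6.92e-05), and not with an estimated correlation (adjusted p = 0.862), and the list means of the mice overlapped between the groups (exact permutation p = 0.6). The version with an estimated correlation called a simulated shift of 0.25 in 0 of 20 runs, so here and below it cannot speak against a list. The preset version called up to 8 lists in splits of the mice that ignore the groups. The list mean of 0.12 includes Foxp2, whose probe was at the floor in HD_miR196a mouse 1 and at 8.94 to 9.84 in the other mice. Without the 13 probes off or on in 1 mouse the mean was 0.23 relative to all genes (adjusted p = 1.93e-05). Without HD mouse 1 the mean relative to all genes became -0.09, or 0.03 with those probes left out as well. Without mouse 1 of each group, the mice with the lowest cortical neuron genes, it was 0.01 and the list was not called. Ppp1r1b, which encodes DARPP-32, differed by 0.48 ± 0.16 (SE), Tac1 by 0.01 ± 0.16, and the Drd2 probe was near the floor in all mice.

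Of 21 genes of oligodendrocytes and myelin, 19 were higher in HD_miR196a mice. Myelin basic protein, Mbp, measured 14.66 ± 0.06 against 14.33 ± 0.12 on its bright probe and differed by 0.01 ± 0.22 (SE) on a dim one. The fatty acid hydroxylase gene Fa2h measured 9.14 ± 0.21 against 8.73 ± 0.24, and no member passed (0 called adjusted over the list alone). Camera called the list with a mean of 0.20 (adjusted p = 0.00191), and not with an estimated correlation (adjusted p = 0.862), and the list means of the mice overlapped (exact permutation p = 0.5). Relative to all genes the mean was 0.21, and the call was lost without HD_miR196a mouse 1 (mean 0.08, adjusted p = 0.243) and without HD mouse 2 (mean 0.04). Without HD mouse 1 the mean was 0.38.

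Interferon-stimulated and antigen presentation genes were mostly lower in HD_miR196a mice, 18 of 24. Irf7, a transcription factor of the interferon response, measured 6.98 ± 0.13 (SD, n = 3) against 7.86 ± 0.09 (SD, n = 2), a difference of -0.88 ± 0.12 (SE). Its adjusted p was 0.694 over all probes and 0.0233 adjusted over the list alone, the only member of 24 under 0.05. Ifit1 differed by -0.61 ± 0.19, the peptide transporter gene Tap1 by -0.57 ± 0.21 and beta-2 microglobulin, B2m, by -0.37 ± 0.16, while Oas2 was higher by 0.22 ± 0.11. Rtp4, an interferon-induced gene outside the list, measured 8.10 ± 0.09 against 9.06 ± 0.27 on 1 probe and differed by 0.12 ± 0.14 on a dimmer one. The list mean was 8.01 ± 0.09 against 8.28 ± 0.11, with every HD_miR196a mouse below both HD mice (exact permutation p = 0.1, the smallest possible). Mouse means did not overlap between the groups for 6 of the 29 lists tested, 20.7%, where chance gives 20%. Camera called the list with a mean of -0.26 (adjusted p = 0.000372), and not with an estimated correlation (adjusted p = 0.737). The call was lost without HD mouse 1 and without mouse 1 of each group, with a mean of -0.19 relative to all genes in each. Over the 21 alternatives that mean ranged from -0.32 to -0.16. For 11 of the 24 genes, Irf7 and Ifit1 among them, the mean level was below the 95th percentile of olfactory receptor probes.

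Inflammation genes were lower in HD_miR196a mice for 21 of 28 members. The chemokine Ccl5 measured 4.93 ± 0.29 against 6.45 ± 0.63 and Tnf 6.87 ± 0.13 against 7.26 ± 0.04, levels within the range of olfactory receptor probes. No member passed adjusted over the list alone. Camera called the list with a mean of -0.18 (adjusted p = 0.0194), and not with an estimated correlation (adjusted p = 0.621, exact permutation p of the list means 0.3). The call was lost without HD_miR196a mouse 1 (mean -0.142 relative to all genes, adjusted p = 0.0621), HD_miR196a mouse 2 (-0.167, 0.0687) or HD mouse 2 (mean -0.057). It was also lost with median centring (-0.15, 0.103), among the 13211 brightest probes (-0.115, 0.29), without scaling (-0.15, 0.244) and with the floor at the olfactory receptor median (-0.157, 0.0579). It held without HD_miR196a mouse 3 (-0.23, 0.0204). The mean was -0.29 without HD mouse 1 and -0.26 without mouse 1 of each group. Genes of apoptosis and the p53 response were lower for 19 of 24 members, among them Cdkn1a, the cell cycle inhibitor p21, at 10.14 ± 0.14 against 10.57 ± 0.18. No member passed adjusted over the list alone, and camera gave a mean of -0.12 (adjusted p = 0.0263), and an adjusted p = 0.621 with an estimated correlation (exact permutation p of the list means 0.2). Leaving out HD_miR196a mouse 1 (adjusted p = 0.134), HD_miR196a mouse 2 (0.0687), HD mouse 1, HD mouse 2 or mouse 1 of each group ended that call, as did the cortical neuron covariate (0.0563). The mean relative to all genes stayed between -0.10 and -0.12 in these fits, against -0.11 with all mice.

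**Figure D2:**
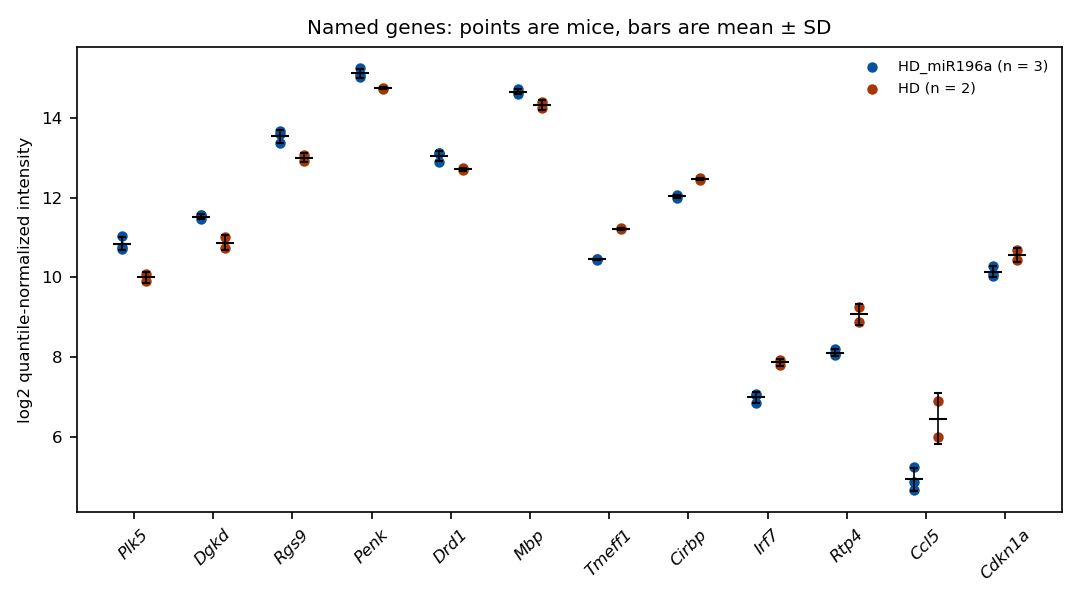
Log2 quantile-normalized intensity (vertical axis) of 12 genes, with a point for each mouse and bars for mean ± SD in HD_miR196a (n = 3) and HD (n = 2). Irf7 lay between 6.83 and 7.08 in HD_miR196a mice and at 7.80 and 7.93 in HD mice, and no gene shown passed the threshold.

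Targets of miR-196 from the literature went both ways, 15 of 31 higher and 16 lower, with a mean of -0.04 (camera adjusted p = 0.762, and 0.865 with an estimated correlation). Ranbp10 measured 11.13 ± 0.07 (SD, n = 3) against 11.06 ± 0.04 (SD, n = 2), with a 95% interval of the difference from -0.18 to 0.32. Hoxc8 differed by 0.02 ± 0.10 (SE) and Hmga2 by -0.05 ± 0.14, both at levels of olfactory receptor probes. Hoxb8, near the floor in both groups, differed by 0.65 ± 0.19 and Abcb9 by 0.24 ± 0.10, while Ing5 differed by -0.31 ± 0.10 and the repressor Bach1 by -0.29 ± 0.11, with no member called adjusted over the list alone. Of the 31 targets, 21 had means below the 95th percentile of olfactory receptor probes, which limits what this list can show. The level of miR-196a itself was not analysed here. The Hox cluster genes, of which 34 of 38 were below that percentile, were higher for 27 members, and none passed adjusted over the list alone. Camera called them with a mean of 0.10 (adjusted p = 0.0194, and 0.621 with an estimated correlation, exact permutation p of the list means 0.2). The call was lost without HD_miR196a mouse 1 (adjusted p = 0.0621), HD_miR196a mouse 2 (0.0687), HD mouse 1 or mouse 1 of each group, where the mean relative to all genes stayed between 0.08 and 0.11. It was also lost with the floor at the olfactory receptor median (mean 0.055, 0.0906). Over the 21 alternatives the mean ranged from 0.06 to 0.35.

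None of the genes named for their role in HD passed. Htt measured 9.34 ± 0.10 against 9.35 ± 0.18, with a 95% interval of the difference from -0.35 to 0.31, and whether its probe also binds the human transgene is not given in the sources used here. Ppargc1a, the coactivator PGC-1alpha, differed by -0.14 ± 0.12 (SE) and Bdnf by -0.11 ± 0.46. The astrocyte gene Gfap measured 8.53 ± 0.38 against 9.10 ± 0.15 and the intermediate filament Vim 12.08 ± 0.22 against 12.52 ± 0.08.

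Markers of other cell types gave no call. Microglia genes had a mean of -0.02 (camera adjusted p = 0.761), endothelium and pericytes 0.04 (0.489), choroid plexus and ependyma 0.08 (0.761), blood 0.22 (0.274, with a mean of 0.46 without mouse 1 of each group), striatal interneurons 0.10 (0.694), and thalamus or pallidum 0.15 (0.694). For astrocytes the mean was 0.33, the median -0.04 and the direction of camera down (adjusted p = 0.5). That mean includes the Slc1a3 probe, which was at the floor in HD mouse 1 and at 12.57 to 13.72 in the other mice, and it was -0.07 relative to all genes without the probes off or on in 1 mouse. Cortical neuron genes, of the region above the striatum, were not called between the groups (mean -0.07, adjusted p = 0.761). Relative to all genes their mean was -0.89 without HD mouse 1, 0.76 without HD mouse 2 and -0.39 without mouse 1 of each group. The estimated correlation of this list was 0.726, which gave an adjusted p = 0.947 with all 5 mice. Their list mean was 8.98 in HD_miR196a mouse 1 and 9.25 in HD mouse 1, and 10.64, 10.33 and 10.87 in HD_miR196a mice 2 and 3 and HD mouse 2.

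**Figure D3:**
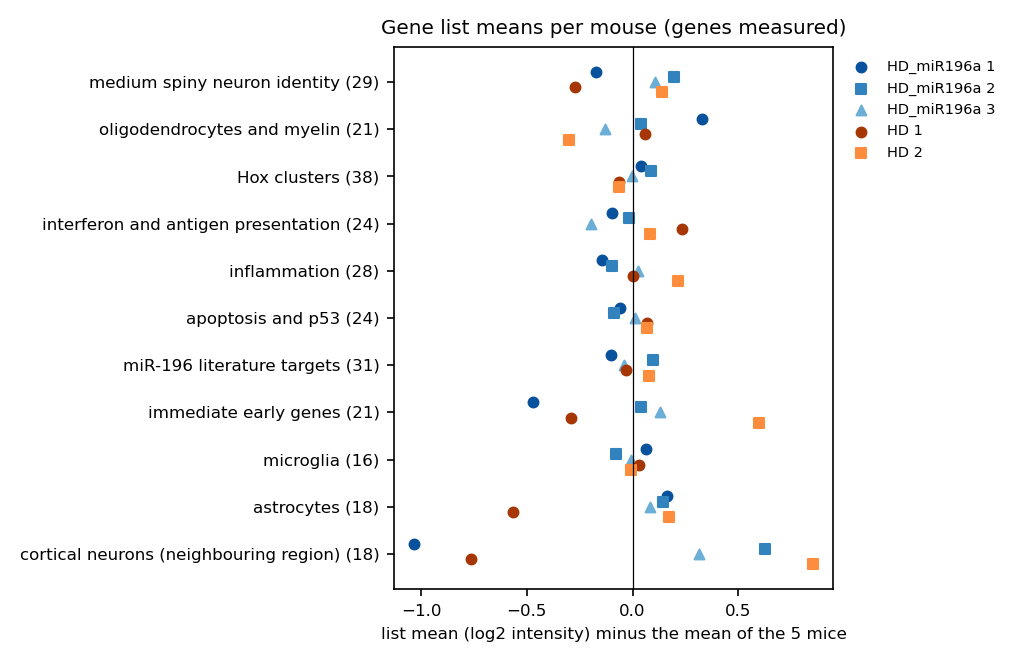
Mean log2 intensity of each gene list in each mouse minus the mean of the 5 mice (horizontal axis), with the number of genes measured in brackets. Interferon genes, Hox cluster genes, and genes of apoptosis and p53 separate the 3 HD_miR196a mice from the 2 HD mice. Of the 29 lists tested, 6 did so (20.7%), where chance gives 20%. Cortical neuron genes separate mouse 1 of each group from the rest.

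**Figure D4:**
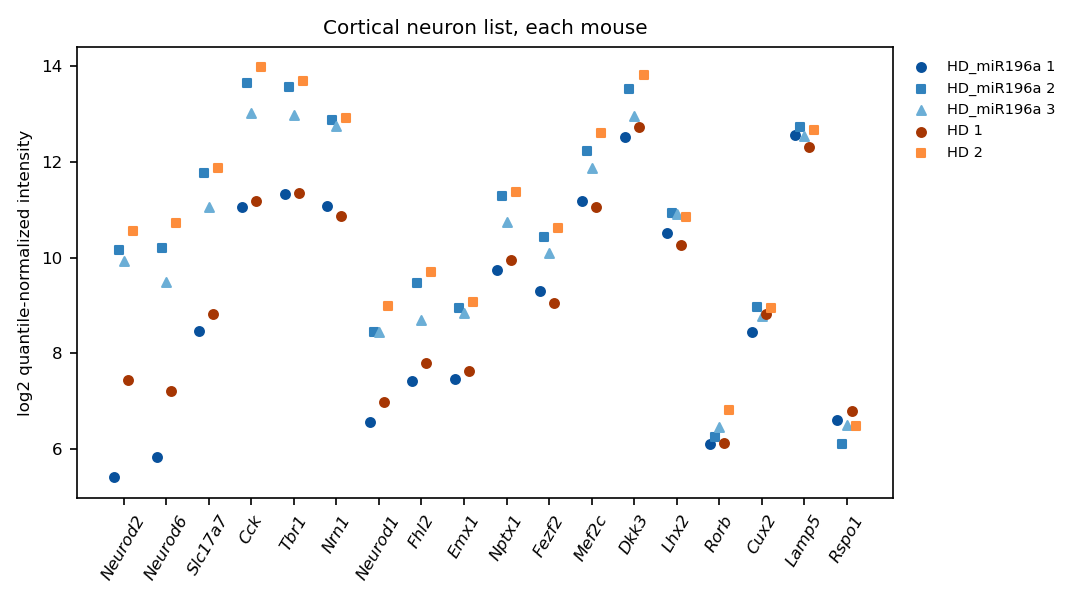
Log2 quantile-normalized intensity (vertical axis) of the 18 cortical neuron genes in each mouse. Neurod6 was at 5.83 and 7.21 in the mice numbered 1 and between 9.49 and 10.73 in the others.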

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

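The settings without scaling, with a higher floor, with a cortical covariate, without mouse 1 of each group and without the 13 probes off or on in 1 mouse were chosen after seeing the data. The count of 0 called probes became 1 among the 19817 probes with the highest mean over all mice (Acot8, which entered that filter only through the HD mice). It became 3 with trend and robust settings, 2 (Tmeff1 and a probe with no gene name) with the higher floor, 2 at an adjusted p under 0.10, and 429 at an unadjusted p under 0.05 with at least a 1.5-fold difference. Leaving out 1 mouse at a time gave 0 to 3: Pitpnm1, Crot and Lrrc8e without HD mouse 1, and Rrp36, Phc1 and Sun2 without HD mouse 2, fits in which the lone HD mouse is assumed to vary like the other group. The probes of Pitpnm1, Crot and Lrrc8e are among the 13 that were off or on in 1 mouse only. Leaving those 13 out removes these calls by construction and is no test of them. The other settings kept 0. The 1099 probes at an unadjusted p under 0.05 became 527 among the 13211 brightest, where fewer probes were tested, and 3641 without scaling, 165 higher and 3476 lower, where the median of all probes shifted by -0.20 on the log2 scale. They were between 740 and 1511 elsewhere apart from the block.

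Across probes, which are not independent replicates, the deviations of mice from their group means had a correlation of 0.236 for the mice numbered 1 and 0.17 for those numbered 2. With 2 HD mice the deviations of 1 mirror those of the other, so these correlations are not independent of each other. Only 2 numbers are shared, and whether equal numbers pair the mice is not given in the sources used here, so pairing stays open. With the replicate block, over 4 or all 5 mice, 0 probes were called, 2020 had an unadjusted p under 0.05 and 10 lists were called. A mouse whose number occurs in only 1 group adds nothing to the group difference in such a fit. Both fits therefore rest on the same 4 mice and are not 2 separate checks. The 4 gained over all 5 mice were cortical neurons (mean -0.25, adjusted p = 0.0106) and immediate early genes (-0.367, 0.0106), both lower, heat shock (0.121, 0.0383) and, lower, cytosolic ribosomal proteins (-0.117, 0.0417).

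The 6 lists called with the preset correlation became 0 with the estimated correlation and 0 with fry, and 2 to 8 with 1 HD_miR196a mouse left out. The estimated version also called 0 lists in every other split of the mice, and the simulated shift in 0 of 20 runs. Its count of 0 here therefore cannot speak against the lists. With 1 mouse left out, the medium spiny neuron mean ranged from -0.093, without HD mouse 1, to 0.34. The cortical neuron mean ranged from -0.89 without HD mouse 1 to 0.76 without HD mouse 2. The cause was not tested beyond the cortical comparison given under the other observations. Of 608 list values under alternatives, 502 kept their direction and side of the threshold, 39 lost a call with the same sign, 23 gained one, 42 changed sign with no call in either fit, and 2 changed sign with a call in 1 of the fits. Of 1637 values of named genes, 1599 stayed, 3 gained a call and 35 changed sign. The seed match test and its alternatives were not run. Low signal limits the interferon, inflammation, Hox and miR-196 target lists.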

Other observations

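All tests of explanations below were chosen after the result was seen. Immediate early genes, which neurons switch on with activity, were lower in HD_miR196a mice for 18 of 21 members, with a mean of -0.25 that camera did not call (adjusted p = 0.134). Fos measured 9.56 ± 0.64 (SD, n = 3) against 10.37 ± 0.76 (SD, n = 2). Without mouse 1 of each group the list mean relative to all genes was -0.51, without HD mouse 1 it was -0.70, and without HD mouse 2 it was 0.21. Each of these fits keeps 1 HD mouse. The estimated correlation of this list was 0.33, which gave an adjusted p of 0.862 with all 5 mice, and none of the 29 lists was called with estimated correlations and all 5 mice. Receptors and scaffolds of glutamate synapses had a mean of 0.07 (adjusted p = 0.336). With 1 mouse left out their mean relative to all genes ranged from -0.14 to 0.28, the highest without HD mouse 2. The mean was 0.06 for synaptic vesicle release (0.595) and 0.09 for GABA signalling (0.5), where Gabrd measured 10.12 ± 0.18 against 9.59 ± 0.55.

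Pathways often studied in HD were not called with quantile normalization and all 5 mice in the fit of the groups alone. The neurotrophin, CREB and PGC-1alpha genes had a mean of -0.05 (camera adjusted p = 0.427), heat shock and the unfolded protein response 0.07 (0.35, and 0.0357 without HD_miR196a mouse 3), and the ubiquitin-proteasome system -0.05 (0.27, and 0.022 with median centring or 0.00644 without scaling), where the proteasome subunit Psmb7 measured 10.33 ± 0.13 against 10.68 ± 0.00. The mean was 0.00 for autophagy and the lysosome (0.927), -0.01 for the mitochondrial respiratory chain (0.694, and 0.0313 without scaling), -0.07 for cytosolic ribosomal proteins (0.318, 0.0437 without HD_miR196a mouse 3, and a mean of -0.127 relative to all genes without HD mouse 2), 0.06 for cholesterol biosynthesis (0.35), -0.01 for cell adhesion (0.761), 0.04 for the cell cycle (0.513, and a mean of 0.169 relative to all genes without HD mouse 2) and 0.02 for the neuronal cytoskeleton (0.761). The median had the opposite sign to the mean for the cytoskeleton and for choroid plexus and ependyma, both -0.01. Ccdc153, a gene of ciliated ependymal cells, was higher in HD_miR196a mice on each of its 2 probes, by 1.12 ± 0.18 and 1.08 ± 0.22 (SE), with an adjusted p of 0.0314 over the choroid plexus and ependyma list alone and 0.824 over all probes, at levels within the range of olfactory receptor probes. The sex-linked list had 2 measured genes and was not tested.

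Cortical neuron genes were lower in mouse 1 of both groups: Tbr1 was at 11.33 and 11.35 in these mice and 12.97 to 13.69 in the others, Cck at 11.05 and 11.18 against 13.01 to 13.97, and Slc17a7 at 8.47 and 8.82 against 11.05 to 11.87. A candidate explanation is different amounts of cortex in the dissected tissue: leaving out Neurod6, through which the pattern was noticed, 14 of 17 cortical genes were lowest in both mice, and the highest of 10000 random lists at the same levels had 9. In both mice 11 of the 18 were above the 95th percentile of olfactory receptor probes, whether from striatum itself or from remaining cortex was not tested, and 2 are in other lists. Scaling is argued against by a median gap of 1.38 in unscaled values, where no random list exceeded 0.26, while the difference between groups of -0.07 says nothing of miR-196a, because the pattern is one shared by a mouse of each group. Immediate early genes were also lowest in both mice for 12 of 21 (median gap 0.72), glutamate synapse genes for 16 of 32 (0.22) and medium spiny neuron genes for 10 of 29 (0.23). The share over all genes was 14%. Gaps of the other sign were found for myelin genes (0 of 21, -0.40), striatal interneurons (4 of 13, -0.35) and thalamus or pallidum (1 of 13, -0.18), among other lists. Neuronal activity or the mice themselves therefore stay open as well.

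The probe of Acot8 and 1 of 2 probes of Lats2, a kinase of the Hippo pathway, were bright in both HD mice and near background in all 3 HD_miR196a mice. Lats2, and Serpina9 and Dapp1 beside it, were chosen after their values were seen. Dapp1 measured 0.54 ± 0.93 in HD_miR196a mice and 6.27 ± 0.71 in HD mice, levels within the range of olfactory receptor probes. With HD_miR196a mice counted at the 95th percentile of olfactory receptor probes, HD mice were at least 2.71-fold higher for Acot8 and at least 2.55-fold higher for Lats2. Independent failures of single spots would give 0.000211 such probes, from the 8 that were dim and the 5 that were bright in 1 mouse only. The 2 genes lie on 2 chromosomes, so 1 genome segment that came with the transgene could not hold both. It could still hold 1 of them, if the other probe reflects a fault of the arrays. Lower messenger RNA cannot be told apart from a fault shared by the arrays of a group, because the other Lats2 probe was near background in HD mice as well (3.35), and such patterns also cross the groups, since the Eid1 probe, chosen after its values were seen, was bright in the mice numbered 1 only (9.92 and 10.23), and slides and print batches are not given in the sources used here.

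The interferon list was lower in HD_miR196a mice for 18 of 24 genes, a call lost with an estimated correlation (adjusted p = 0.737). Scaling is argued against by unscaled values, where the list median was -0.41 and that of all genes -0.21, a difference of -0.20, and the lowest median of 10000 random lists at the same levels was -0.37. Fewer microglia could contribute and cannot be excluded: the microglia median was -0.03 (bootstrap interval over genes -0.20 to 0.07), and its difference from the interferon median ranged from -0.02 to 0.40. Of the 10 splits of the 5 mice, 1, the real one, gave a list mean as far from 0 (-0.263, and 0.25 at most in the others), too few splits for a share under 0.05. At the preset correlation camera also called the list in splits that ignore the groups, with adjusted p-values of 0.000899, 0.0191 and 0.0212. An effect of miR-196a and differences of housing or infection were not tested.

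Over the whole array, 5 of the 10 splits gave at least the 1099 probes of the real one at an unadjusted p under 0.05, with 2656 for mouse 1 of each group against the rest, and 4 gave at least 6 called lists, with at most 8. The number of splits is too small for a share under 0.05, and the split with 2656 probes follows the cortical difference described above. Single spots dim in 1 mouse only included Slc1a3 and Sun2 in HD mouse 1, and Pitpnm1, Hnrnpd, Brsk2, Crot and Lrrc8e in HD mouse 2.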
